A study of Mus musculus with 16 samples.

How the data were processed

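Whole adrenal glands of mouse embryos were profiled on Affymetrix Mouse430_2 arrays, which measure transcripts with probe sets of short oligonucleotides. The knockout carried a Cre transgene driven by the Sf1 regulatory region together with floxed Dicer alleles, so that Dicer, the enzyme that cuts microRNA precursors into mature microRNAs, was deleted where Sf1 is active, which includes the adrenal cortex. Controls were littermates without the transgene, on a C57BL/6 background, and the labels call them wild type. Per the labels, glands of the same genotype within a litter were pooled, 4 litters were used at each of embryonic days E15.5 and E16.5, and each pool went on 1 array. The 16 arrays thus fell into 4 groups of 4 pools from separate litters, and the spread between them includes the variation between litters. The labels number the pools but do not say that a number marks a litter.

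The values used were log2 signals of 45101 probe sets, deposited by the authors as a table of normalized values and made with RMA, per the submitters' processing notes, which also name limma. No version is given for either in the sources used here, nor is it stated whether all 16 arrays were normalized in a single run. RMA subtracts background, gives arrays a common distribution of probe intensities and summarises the probes of each set on the log2 scale. Dim probe sets are compressed towards the background level by this summary, so that the change of a transcript near the floor is understated. The deposited values were used without further normalization.

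Gene names came from the platform annotation paired with the table. Of the probe sets other than the 64 control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were brought up to date through the gene identifier for 34741 of them. Probe sets with several symbols or none named no gene. For each of 18193 genes the probe set with the highest mean over the 16 arrays was kept. A gene was tested when that probe set lay above the 40th percentile of an array on at least 4 arrays, which left 13642 genes tested and 4551 below the filter. Some named genes were carried by other probe sets as well. Of 17 other probe sets for 12 named genes of the knockout comparisons, 1 had the opposite sign with an unadjusted p under 0.05 at either stage. The gene of that probe set is not singled out below. Fold changes below are those of the kept probe set unless a further probe set is named.

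Differences were tested with limma 3.58.1 in R 4.3.3, and tables were read with the data.table package (1.17.8). A linear model with a mean for each of the 4 groups was fitted to all 16 arrays, so that the groups share an estimate of the spread, and was moderated with eBayes. The Benjamini-Hochberg adjustment ran over all genes tested, and a gene passed at an adjusted p under 0.05. All limma tests were two-sided. Every adjusted p of a gene below comes from this fit unless an array left out or the offset allowance is named beside it. A log2 fold change is followed by its standard error (SE) where given. The contrasts were knockout against control at each stage, the difference between those effects, and E16.5 against E15.5 within each genotype. The number of arrays limits the precision: the median SE of a knockout effect was 0.139 on the log2 scale.

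There were 23 gene lists: steroidogenesis, cholesterol synthesis, subcapsular hedgehog and Wnt signalling, capsule and mesenchyme, chromaffin cells, Schwann lineage, erythroid cells, endothelium, macrophages, kidney, gonad and germ cells, liver, p53 targets and apoptosis, cell proliferation, targets of let-7, of miR-34 and of miR-21, microRNA machinery, microRNA host transcripts, interferon response, stress response, imprinted growth genes, and the sex composition of the pools. Each was tested with camera from limma at its preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry as alternatives. Camera compares the members of a list with all other genes tested. The counts of passing members were also taken with the p-values adjusted over the list alone.

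Named genes were chosen by a rule. For each knockout comparison these were the 10 genes with the largest rise and the 10 with the largest fall among genes that passed and whose 4 knockout values all lay on the same side of the 4 control values, and for each stage comparison 5 and 5. Where no gene passed, the 3 genes with the smallest p were named as values. Of each list, up to 4 members with the largest change could be named, and Dicer1, Nr5a1, Nr6a1, Acvr1c, Cdkn1a and Pcna were always looked at; a further gene of that rule is not reported here. List members beyond those 4 that are named below were chosen after their values were seen. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

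The fit was tested on simulated data in which 200 of 13642 genes were changed, in each comparison. At a log2 change of 1, 88.1% of the changed genes were recovered for knockout against control at E15.5, 92.5% at E16.5, 95.5% for the day in controls and 85.1% for the day in knockouts. At a log2 change of 0.5 the shares were 38.8%, 34.3%, 43.3% and 31.3%. False calls numbered 5, 5, 14 and 5 of 154, 156, 169 and 149 calls. The simulated values were drawn independently for each gene and array around the mean of the gene. They held no offset between genotypes, no correlation between genes and no array of poor quality. These shares and false calls therefore describe the fit in that setting and not the real comparisons.

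Alternatives were no filter on dim probe sets and a filter at the 60th percentile, quantile normalization of the 16 arrays again, centring of each array on its median or 75th percentile, other rules for the probe set of a gene, eBayes with trend and robust settings, arrayWeights, a fit to only the 8 arrays compared, the sex score of the pools or the 3′ minus 5′ signal as a covariate, a threshold that adds an absolute log2 fold change of at least 1, the replicate number as a block, and each array left out in turn. Added after the data were seen were an allowance for an offset between the genotypes, fits without control E16.5 replicates 1 and 2 (for lists also without either, at both correlations), and a fit without genes on the X and Y chromosomes. The offset was estimated from the 9008 probe sets with the lowest means (the dimmest 20%). The allowance centred each knockout effect on their median effect and widened its SE by the spread of their effects beyond sampling error. The sex score was the mean of the Y-linked genes measured minus Xist, and the 3′ minus 5′ signal was the difference between control probe sets at either end of Actb and Gapdh, which grows as RNA degrades. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The planned analysis of microRNA seed matches in 3′ untranslated regions was not run, because transcript sequences were not used here.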

Results

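The data were 16 arrays of pooled mouse adrenal glands, 4 per group: control and Dicer knockout (KO) at E15.5, and control and KO at E16.5. The comparison between genotypes asks which transcripts change in the developing gland when Dicer is deleted in cells that use Sf1, and the comparison between stages asks what changes over 1 day of development. Values are log2 signals, so a difference of 1 is a doubling. Correlations between arrays of a group ranged from 0.95 to 0.99. The lowest were those of control E16.5 replicate 2, whose 3′ minus 5′ signal was 3.15 against 0.19 to 1.62 in the other 15 arrays.

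The KO arrays had a slightly higher mean signal. Means over all probe sets were 6.35 to 6.37 in the 8 KO arrays and 6.31 to 6.32 in the 8 controls, without overlap (exact permutation p = 0.0286 at each stage, two-sided, the smallest that 4 against 4 arrays allow; 0.0571 after Benjamini-Hochberg adjustment over 6 tests of array-wide values). Among the 9008 dimmest probe sets, 31.7% at E15.5 and 28.3% at E16.5 had an unadjusted p under 0.05 for KO against control, while 2.88% and 2.60% did for the day in controls and in KO. This offset between genotypes bears on genes with small changes. Counts of passing genes in the comparisons of genotypes below therefore come with counts that allow for it. The allowance at a stage is the same for all genes and need not remove the offset in full.

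**Figure D1:**
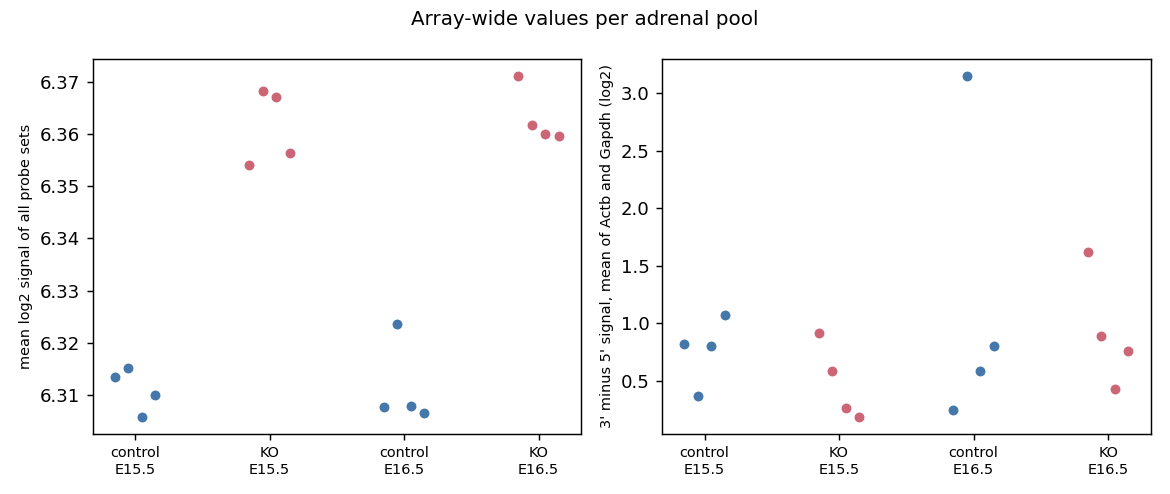
Array-wide values of the 16 adrenal pools, in 4 groups of 4 (blue, control; red, KO; a point is an array). Left, mean log2 signal over all probe sets, where the KO arrays lie at 6.35 to 6.37 and the controls at 6.31 to 6.32; the axis does not start at 0. Right, 3′ minus 5′ signal on the log2 scale, mean of Actb and Gapdh, with control E16.5 replicate 2 at 3.15.

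Dicer1 itself fell slightly in KO glands at E16.5, and its lower value at E15.5 did not pass. At E15.5 its log2 signal was 8.23 ± 0.16 (SD, n = 4) in KO and 8.59 ± 0.07 in controls, a log2 fold change of −0.35 (SE 0.11, adjusted p = 0.0638). At E16.5 it was 8.26 ± 0.14 against 8.62 ± 0.16, a change of −0.36 (adjusted p = 0.0414, and 0.515 with the offset allowed for). All 4 KO values lay below all 4 control values at each stage. A further Dicer1 probe set differed by −0.35 and −0.42. Where these probe sets lie relative to the deleted part is not given in the sources used here, so the check of the labels that they give is limited. Nr5a1, which encodes Sf1, the nuclear receptor that directs steroidogenic cells, differed by 0.56 (SE 0.33, adjusted p = 0.396) at E15.5 and 0.19 (adjusted p = 0.797) at E16.5.

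**Figure D2:**
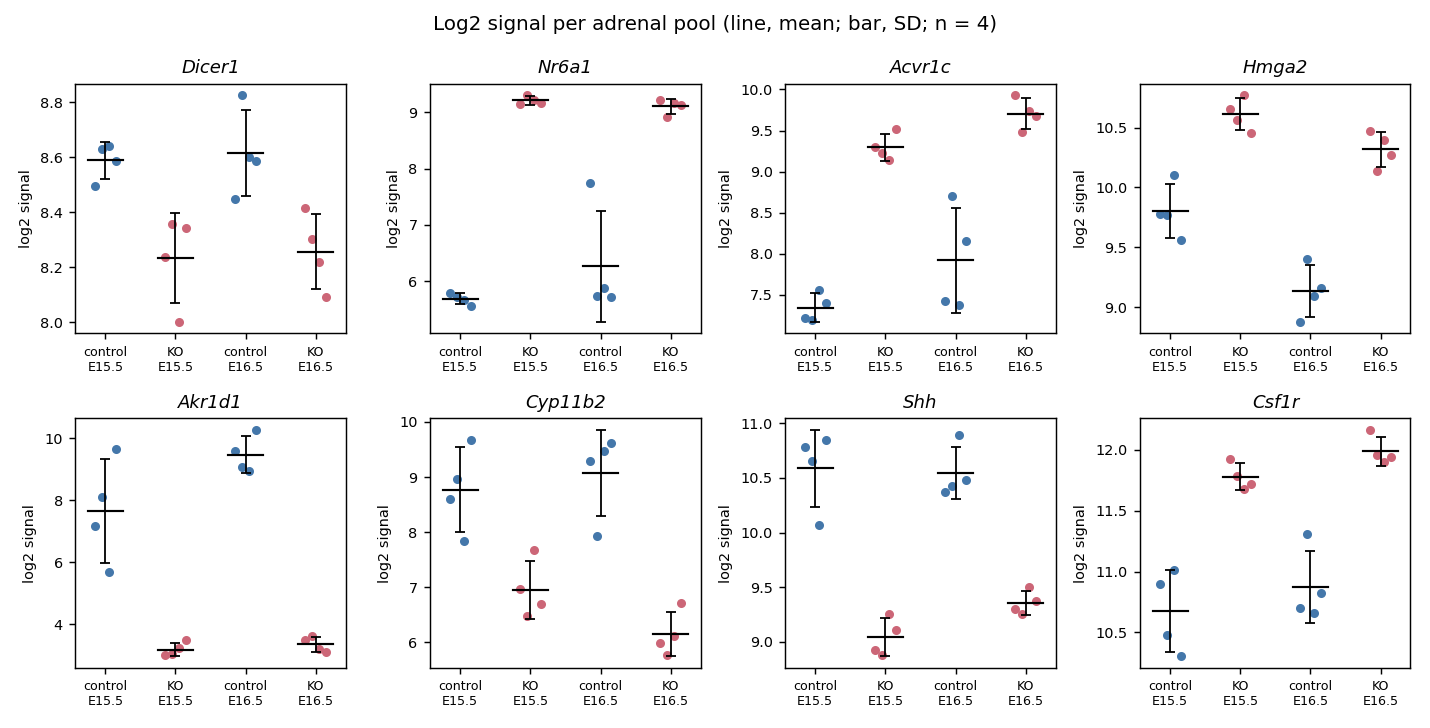
Log2 signal of 8 genes in each adrenal pool (blue, control; red, KO; line, mean; bar, SD; n = 4 per group), each panel with its own axis that does not start at 0. In every panel the KO values at a stage lie outside the range of the controls of that stage; for Nr6a1 the KO means are 9.21 and 9.11 against control means of 5.69 and 6.27.

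At E15.5 the largest rise in KO glands was that of Nr6a1, an orphan nuclear receptor also known as germ cell nuclear factor. Its log2 signal was 9.21 ± 0.07 in KO and 5.69 ± 0.10 in controls, a log2 fold change of 3.53 (SE 0.31, adjusted p = 5.30e-06, n = 4 per group). Igdcc3, a membrane protein of the immunoglobulin superfamily, rose by 2.32 (SE 0.16, adjusted p = 3.86e-07). The other large rises were those of Cited1, a transcriptional co-regulator (2.08), Trim6, a ubiquitin ligase (2.02), Crym, which binds thyroid hormone (1.98), Acvr1c, a receptor of the activin and nodal family (1.95), Ppp1r36 (1.93), Greb1l (1.92), the cystine transporter Slc7a11 (1.71) and Procr, the receptor of protein C (1.69), with adjusted p from 3.21e-07 to 0.000149.

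The largest fall at E15.5 was that of Akr1d1, a reductase that inactivates steroid hormones. Its log2 signal was 3.19 ± 0.22 in KO and 7.65 ± 1.67 in controls, a change of −4.47 (SE 0.56, adjusted p = 0.000105, n = 4 per group), which was −5.12 without control replicate 3 and −3.8 without control replicate 4. Frzb, a secreted antagonist of Wnt signalling, fell by 2.76 (SE 0.30, adjusted p = 2.97e-05). Falls were also measured for Adh7, an alcohol dehydrogenase that oxidises retinol (−2.47), the drug transporter Abcb1b (−2.25), the monooxygenase Cyp2f2 (−2.11), the kinase Sgk2 (−2.07), Aard (−2.01), the bone sialoprotein gene Ibsp (−1.94) and the glutathione transferase Mgst2 (−1.85). Cyp11b2, the aldosterone synthase, fell by 1.82 (SE 0.40, adjusted p = 0.0105). All 20 of these genes also passed with the genotype offset allowed for.

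Among the lists at E15.5, 8 of 15 macrophage genes rose, and 13 did when adjusted over the list alone, with a median of 0.81 (camera adjusted p = 9.58e-09; adjusted p = 0.0971 with an estimated correlation). Examples were Csf1r, the receptor of colony-stimulating factor (1.10), and Aif1 (1.09). With the offset allowed for, 1 macrophage gene passed. The calls of C1qb and Fcgr3 were each lost in 7 of the 8 fits that left out 1 array. Those of C1qc and Cd68, both higher, were added without KO replicate 1. Targets of the let-7 microRNA family rose in 8 of 22 cases and fell in 1, Ccnd2 (−0.38, a call lost in 7 of the 8 fits that left out 1 array); adjusted over the list alone 12 rose and 1 fell (median 0.34, camera adjusted p = 7.46e-05; adjusted p = 0.0642 with an estimated correlation; 3 higher with the offset allowed for). After Nr6a1 and Acvr1c these included the chromatin regulators Arid3b (1.52) and Hmga2 (0.81). The study singled out Nr6a1 and Acvr1c on these arrays, so they are not independent evidence of the direction. Without them 6 of 20 rose and 1 fell. Nr6a1 and Acvr1c were both among the 3 let-7 targets that passed with the offset allowed for. Of the p53 targets and apoptosis genes 5 of 22 rose and 7 did adjusted over the list alone (median 0.17, camera adjusted p = 0.00774; adjusted p = 0.168 with an estimated correlation; 0 with the offset allowed for, against 8 higher and 1 lower at an unadjusted p under 0.05 in limma). They were Cdkn1a, the cyclin-dependent kinase inhibitor p21 (1.53, adjusted p = 0.00846, and 0.0857 with the offset allowed for), Btg2 (1.11), Eda2r (1.00), Ccng1 (0.77) and Zmat3 (0.59).

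Some genes of steroid synthesis fell at E15.5. In the steroidogenesis list 5 of 19 fell and none rose; adjusted over the list alone 8 fell and 1 rose (median −0.31, camera adjusted p = 5.51e-06; adjusted p = 0.168 with an estimated correlation; 3 lower with the offset allowed for). Besides Cyp11b2 these were Akr1c18, which inactivates progesterone (−1.76), Nr0b1, the Dax1 repressor (−1.34), Cyp11b1, which makes corticosterone (−0.94), and Hsd3b1 (−0.32). Star, the cholesterol carrier into mitochondria, differed by 0.19, Cyp11a1, the side-chain cleavage enzyme, by −0.33 and Cyp17a1 by 0.83, none of which passed. In the subcapsular list of hedgehog and Wnt signalling 4 of 15 fell, also when adjusted over the list alone: the ligand Shh (−1.54, adjusted p = 1.76e-05), its antagonist Hhip (−0.85), Dab2 (−0.64) and the receptor Ptch1 (−0.36). That list's median was 0.03, which became −0.04 after quantile normalization and with arrays centred on their 75th percentile, while its mean was −0.16 and camera pointed down (adjusted p = 0.0231; adjusted p = 0.480 with an estimated correlation; 1 lower, Shh, with the offset allowed for). With 1 array left out 3 to 7 steroidogenic genes fell, fewest without control replicate 1 or KO replicate 2, and 2 to 4 subcapsular genes, fewest without control replicate 1, 3 or 4 or KO replicate 1 or 2. The calls of Akr1c18, Hsd3b1, Dab2 and Ptch1 were lost in 3 to 6 of these 8 fits, and that of the steroidogenic gene that rose adjusted over the list alone in 4.

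In the other lists few or no members passed at E15.5. For chromaffin genes, those of the catecholamine-producing medulla, 0 of 19 passed in limma or adjusted over the list alone, against 3 at an unadjusted p under 0.05, with a median of 0.31 (camera adjusted p = 0.0186; adjusted p = 0.754 with an estimated correlation). For proliferation genes 0 of 25 passed by either count against 5 at an unadjusted p under 0.05 (median 0.18, camera adjusted p = 0.0527), and Pcna, a clamp of DNA replication, differed by 0.17 (adjusted p = 0.83). No member passed by either count among cholesterol synthesis (20 genes tested), capsule and mesenchyme (16), Schwann lineage (6), erythroid (9), endothelial (12), liver (9), miR-34 target (18), microRNA host (7), imprinted (11) and sex composition (4) genes, with 1, 1, 0, 1, 0, 0, 2, 1, 1 and 0 at an unadjusted p under 0.05 and camera adjusted p from 0.83 to 0.98. Of the 4 gonad genes tested 0 passed and 2 did when adjusted over the list alone (camera adjusted p = 0.236). Single genes rose in the kidney list (Cited1, of 9), the miR-21 target list (Btg2, of 11), the microRNA machinery list (Tarbp2, 0.69, of 14) and the interferon list (Oas1a, 0.48, of 13), and Dnajb9 (0.77) and Atf3 (0.69) rose among 15 stress genes (camera adjusted p from 0.404 to 0.966). Adjusted over the list alone the counts were the same, except that 1 interferon gene fell as well. With the offset allowed for Cited1 passed, and 0 of the miR-21, machinery, interferon and stress genes did, against 3, 4, 2 and 4 at an unadjusted p under 0.05 in limma. The call of Oas1a was lost in 7 of the 8 fits that left out 1 array. Calls added by leaving out an array were those of Wt1 in the capsule list (without control replicate 3), Tspo2 in the erythroid list (without KO replicate 2), Foxl2 in the gonad list (without control or KO replicate 2) and Ago2 in the machinery list (without control replicate 4). Adjusted over the list alone, leaving out an array moved the counts of these lists by at most 1 gene in a direction, except that the gonad list lost both of its genes without replicate 3 or 4 of either genotype.

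In all, 800 of 13642 genes passed in limma at E15.5, 503 higher and 297 lower in KO, and 117 of these changed at least 2-fold, 57 higher and 60 lower. With the genotype offset allowed for, 118 passed, 44 higher and 74 lower. The split was 373 higher to 350 lower after quantile normalization and 276 to 372 with arrays centred on their 75th percentile, against 503 to 297 as deposited. The count was 1688 without the filter on dim probe sets, 414 with the stricter filter and 1350 with arrayWeights.

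At E16.5 the largest rise was again that of Nr6a1, by 2.84 (SE 0.31, adjusted p = 1.88e-05, n = 4 per group), from 6.27 ± 0.99 in controls to 9.11 ± 0.13 in KO. Control replicate 1 stood at 7.75 and the other 3 at 5.71 to 5.87. Lgals3, a galectin abundant in macrophages, rose by 2.43 (adjusted p = 1.96e-06), from 7.47 ± 0.38 to 9.90 ± 0.18. Further rises were those of Igdcc3 (2.36), the annexin Anxa13 (2.21), Trim6 (2.14), Crym (1.99), Greb1l (1.95), the chemokine Ccl6 (1.89), Rgs1, a regulator of G-protein signalling in leukocytes (1.88), and Ppp1r36 (1.82), with adjusted p from 3.35e-07 to 2.73e-05.

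Akr1d1 had the largest fall at E16.5, of −6.12 (SE 0.56, adjusted p = 2.63e-06, n = 4 per group), with 3.35 ± 0.24 in KO and 9.47 ± 0.60 in controls. Cyp2f2 fell by 3.74 (adjusted p = 5.63e-07) and Akr1c18 fell by 2.97 (SE 0.41, adjusted p = 0.000170). Cyp11b2 fell by 2.93 (SE 0.40, adjusted p = 0.000136). The Cyp11b2 signal was 6.15 ± 0.40 in KO and 9.08 ± 0.78 in controls. Frzb (−2.70), Adh7 (−2.66), Sgk2 (−2.51), Ms4a10 (−2.50), Aard (−2.46) and the stress-activated kinase Mapk13 (−2.33) also fell. All 20 of these genes passed with the offset allowed for. Single arrays stood apart from the other 3 of their group for Aard and Trim6 (control replicate 4) and Ppp1r36 (KO replicate 2).

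Macrophage genes rose almost throughout at E16.5: 14 of 15 passed, also when adjusted over the list alone, with a median of 1.32 (camera adjusted p = 1.83e-13; adjusted p = 0.0237 with an estimated correlation), and 10 passed with the offset allowed for. Without control replicate 2 the adjusted p with an estimated correlation was 0.0569 for macrophage genes and for let-7 targets. The largest were Cd68, a lysosomal protein of macrophages (1.68), the complement genes C1qa (1.67) and C1qc (1.56), and Tyrobp (1.49). The exception was Cd14 (−0.14). The mean of the 9 erythroid genes, of which 0 passed in limma against 3 at an unadjusted p under 0.05, was higher by 0.57. Targets of let-7 rose in 11 of 22 cases; adjusted over the list alone 12 rose and 1 fell (median 0.44, camera adjusted p = 1.67e-05; adjusted p = 0.0237 with an estimated correlation; 5 higher with the offset allowed for). Acvr1c rose by 1.78, Hmga2 by 1.19, Arid3b by 1.18 and Plagl2 by 1.09, and without Nr6a1 and Acvr1c 9 of 20 rose. Nr6a1 was among the 5 let-7 targets that passed with the offset allowed for. Of the p53 targets and apoptosis genes 6 of 22 rose, among them Btg2 (1.27) and Eda2r (1.03), and 1 fell, Trp53inp1 (−0.45); adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 0.0159; adjusted p = 0.20 with an estimated correlation; 2 higher with the offset allowed for). The call of Trp53inp1 was lost in 4 of the 8 fits that left out 1 array and that of Sesn2, which rose by 0.77, in 5. Adjusted over the list alone 2 of these genes fell without control replicate 1 or KO replicate 2, and 2 let-7 targets without control replicate 2, while 1 let-7 target fell in limma without control replicate 1. Cdkn1a differed by 1.00 (adjusted p = 0.0609), and by 1.41 (adjusted p = 0.000793) without control replicate 2.

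**Figure D3:**
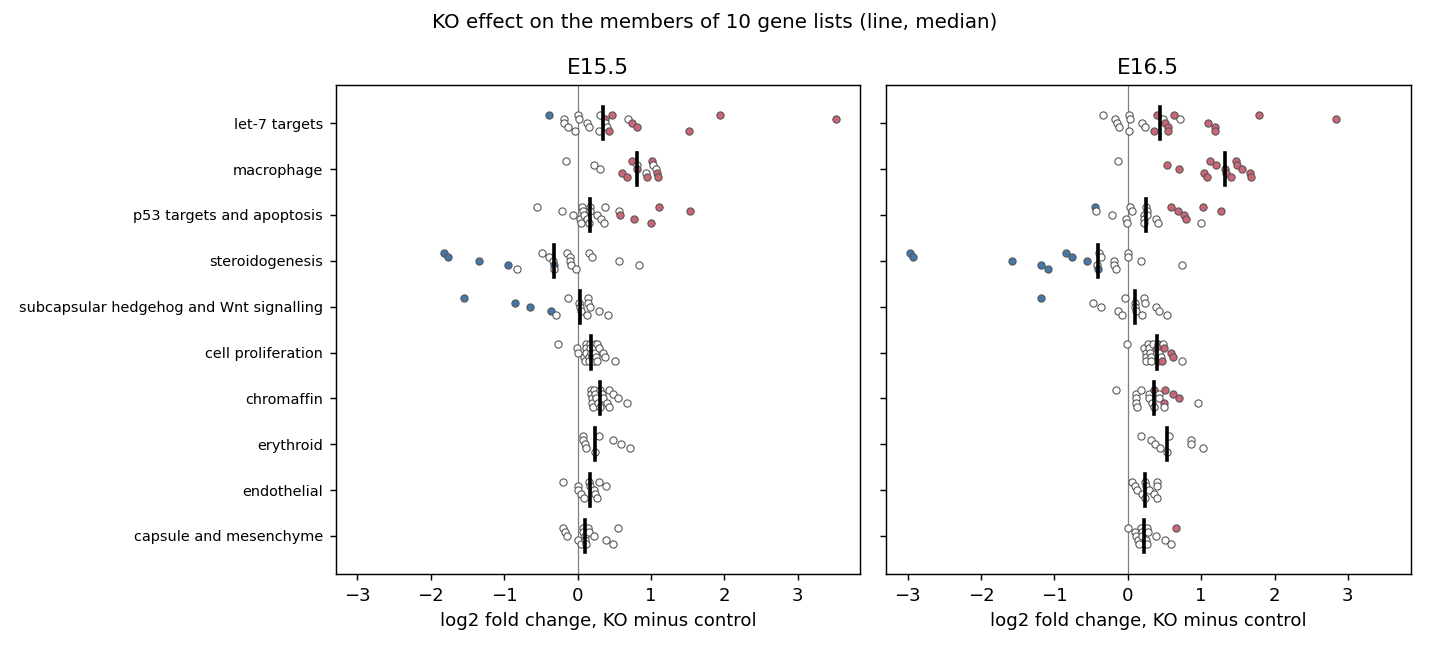
KO effect on the members of 10 gene lists at E15.5 (left) and E16.5 (right); the x axis is the log2 fold change of KO minus control, a point is a gene (red, higher and blue, lower at an adjusted p under 0.05; open, not passing; no allowance for the genotype offset) and the line is the list's median. Macrophage medians lie at 0.81 and 1.32, steroidogenesis medians at −0.31 and −0.40; the subcapsular median at E15.5, 0.03, changed sign under other scalings of the arrays.

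In the steroidogenesis list 9 of 19 genes fell at E16.5 and none rose, and adjusted over the list alone 10 fell and 1 rose (median −0.40, camera adjusted p = 7.31e-11; adjusted p = 0.0314 with an estimated correlation; 5 lower with the offset allowed for). Besides Akr1c18 and Cyp11b2 these included Cyp11b1 (−1.58), Nr0b1 (−1.19), the hydroxylase Cyp21a1 (−1.09), and the corticotropin receptor Mc2r (−0.77) with its accessory protein Mrap (−0.56). Star (0.00), Cyp11a1 (−0.37) and Cyp17a1 (0.75) did not pass. The list's adjusted p with an estimated correlation was 0.0533 without control replicate 1 and 0.0569 without replicate 2, and the call of Mrap was lost in 5 of the 8 fits that left out 1 array, while the rise adjusted over the list alone was lost in 4 of them. Of 15 subcapsular genes 1, Shh (−1.18), fell by either count and with the offset allowed for (median 0.09, mean −0.00, camera pointing down, adjusted p = 0.529). Without control replicate 1 Hhip fell as well (−0.61, adjusted p = 0.0221), and without KO replicate 2 Lgr5 rose (0.68, adjusted p = 0.0449). By the count over the list alone 2 subcapsular genes fell without control replicate 1 or KO replicate 2, and 1 rose without KO replicate 2 or control replicate 4.

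Some proliferation and medulla genes also passed at E16.5. Of 25 proliferation genes 8 rose, 14 adjusted over the list alone, among them the mitotic kinase Aurka (0.61), Ccne1 (0.58) and the replication helicase gene Mcm5 (0.49); the median was 0.40 (camera adjusted p = 4.02e-06; adjusted p = 0.132 with an estimated correlation). Pcna differed by 0.32 (adjusted p = 0.563), with control replicate 2 at 11.05 and the other 3 controls at 12.61 to 12.72. Of 19 chromaffin genes 5 rose, 7 adjusted over the list alone, such as the granin genes Chga (0.69) and Scg2 (0.61); the median was 0.36 (camera adjusted p = 0.0159; adjusted p = 0.638 with an estimated correlation). Of 20 cholesterol genes 3 rose by either count, Hsd17b7 (1.12), Insig1 (0.74) and Fdft1 (0.49), with a median of 0.28 (camera adjusted p = 0.0228; adjusted p = 0.638 with an estimated correlation). With the offset allowed for, 0 members of these 3 lists passed, against 16, 8 and 8 at an unadjusted p under 0.05 in limma. Without control E16.5 replicates 1 and 2, whose values stand apart, 3 proliferation, 0 chromaffin (5 at an unadjusted p under 0.05 in limma) and 2 cholesterol genes rose, against 14 macrophage and 8 let-7 target genes that rose and 8 steroidogenic genes that fell. With 1 array left out 4 to 8 proliferation genes (fewest without KO replicate 1), 1 to 4 chromaffin genes (fewest without KO replicate 3) and 1 to 5 cholesterol genes rose (fewest without KO replicate 1, most without control replicate 1). The counts adjusted over the list alone were then 9 to 14 (fewest without control replicate 1), 3 to 7 (fewest without control replicate 2) and 2 to 9 (most without control replicate 1). Without control replicate 2 the camera adjusted p of the chromaffin and cholesterol lists was 0.254.

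Further lists at E16.5 held few passing genes, with camera adjusted p from 0.0977 to 0.817. These were Rspo3 (0.66) of 16 capsule genes, Erbb3 (0.50) of 6 Schwann genes (3 adjusted over the list alone), Foxl2 (0.44) of 4 gonad genes, Dll1 (0.45) of 18 miR-34 targets (2 adjusted over the list alone), Btg2 and Reck (0.51) of 11 miR-21 targets (3 adjusted over the list alone), Tnrc6a (0.75), Tnrc6b (0.71) and Tarbp2 (0.62) of 14 machinery genes, Oas1a (0.53) of 13 interferon genes, and Dnajb9 (0.77) and Atf3 (0.73) of 15 stress genes. In the kidney list Cited1 (1.42) and Foxd1 (0.40) rose and Aqp2 (−0.56) fell, of 9, and Mir22hg fell among 7 microRNA host genes, where 1 more rose adjusted over the list alone. No member passed by either count among 9 erythroid, 12 endothelial, 9 liver, 11 imprinted and 4 sex composition genes, with 3, 3, 0, 2 and 1 at an unadjusted p under 0.05 in limma. Without control replicate 1, however, 2 of the 9 erythroid genes rose, 5 adjusted over the list alone: Hbb-y by 1.85 (adjusted p = 0.00679) and Hbb-bh1 by 1.13 (adjusted p = 0.0281), with a camera adjusted p of 0.00584 (adjusted p = 0.292 with an estimated correlation). That fit kept KO replicate 1, with Hbb-y at 11.91 against 9.79 to 10.16 in the other KO arrays at E16.5. In the same fit interferon genes had a camera adjusted p of 0.0487 (adjusted p = 0.480 with an estimated correlation).

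With the offset allowed for, Btg2 of the miR-21 targets and Cited1 of the kidney list passed at E16.5. None of the capsule, Schwann, gonad, miR-34, machinery, interferon, stress and host genes then did, against 3, 3, 2, 3, 4, 4, 2 and 2 at an unadjusted p under 0.05 in limma. The calls of Erbb3, Foxl2, Dll1, Tnrc6b, Oas1a, Foxd1, Aqp2 and Mir22hg were lost in 1 to 7 of the 8 fits that left out 1 array. Calls added in this way were those of Tek (endothelial list), Sox10 and Cdh19 (Schwann), Amh (gonad), Wt1 and Postn (capsule), Notch1 (miR-34), Peli1 (miR-21), and Rsad2 and Ifit3 (interferon), all higher in KO and each without 1 or 2 of the 8 arrays. Adjusted over the list alone, the count of genes that rose reached 8 in the machinery list and 3 in the gonad list without control replicate 2, and 5 in the interferon list and 2 in the endothelial list without KO replicate 2. The 3 Schwann genes were lost without control replicate 1, and capsule, kidney, miR-34, host and stress counts moved by 1 or 2 genes.

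The KO pools at E16.5 had a lower sex score, that is, more Xist relative to Y-linked signal, −5.47 ± 2.91 against 0.62 ± 3.84 in controls (exact permutation p = 0.0286, two-sided, 0.0571 after adjustment over the 6 array-wide tests), while at E15.5 the scores were −2.49 ± 3.8 and 0.41 ± 6.27 (exact permutation p = 0.400, 0.480 adjusted).

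In limma, 1439 of 13642 genes passed at E16.5, 954 higher and 485 lower in KO, and 208 of these changed at least 2-fold, 123 higher and 85 lower. With the offset allowed for, 251 passed, 132 higher and 119 lower. The split was 606 higher to 571 lower after quantile normalization and 449 to 605 with arrays centred on their 75th percentile, against 954 to 485 as deposited. The count was 926 with the sex score as a covariate, 935 without KO E16.5 replicate 3, 817 in a fit to the 8 arrays alone, 2355 without the filter, 899 with the stricter filter and 4938 with arrayWeights.

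Genes changed at both stages outnumbered what independent lists would share. Of the 503 genes higher at E15.5 and the 954 higher at E16.5, 395 were shared, against 35.2 for independent lists. Of the 297 and 485 lower genes, 249 were shared against 10.6, and 0 genes passed in opposite directions. With the offset allowed for, 43 of 44 and 132 higher genes and 66 of 74 and 119 lower genes were shared, against 0.426 and 0.646. Across the 13642 genes the effects correlated with a Pearson r of 0.795 and a Spearman rho of 0.712; genes are not independent replicates, and although the 2 comparisons share no array, both carry the offset between genotypes.

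**Figure D4:**
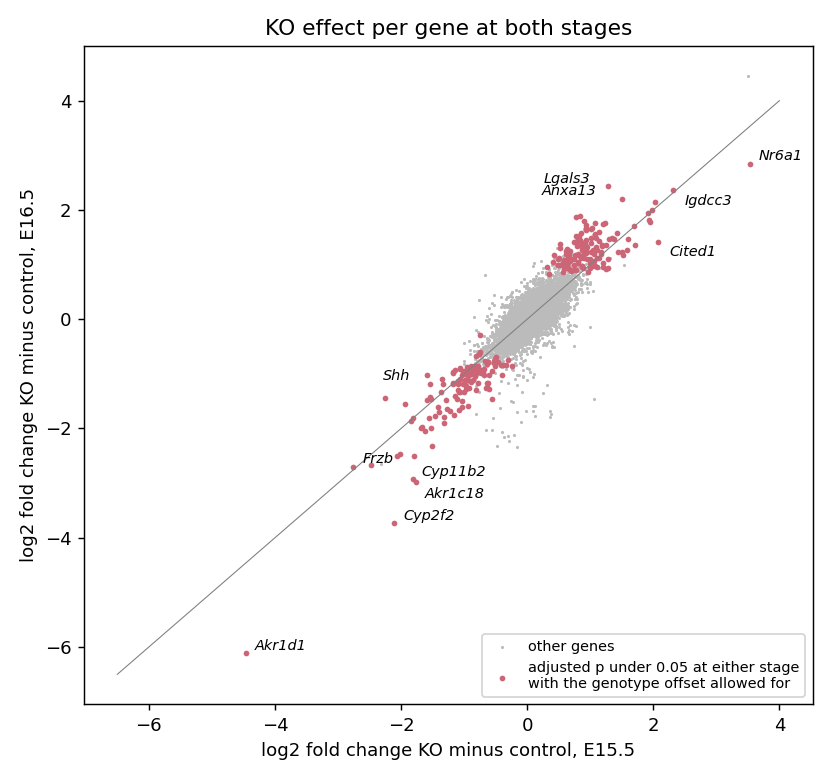
KO effect of each of 13642 genes at E15.5 (x axis) and E16.5 (y axis), as the log2 fold change of KO minus control; red points passed at either stage with the genotype offset allowed for, grey points are all other genes, and the line marks equal effects. Nr6a1 lies at 3.53 and 2.84, and Akr1d1 at −4.47 and −6.12.

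No gene's KO effect was shown to differ between stages: 0 of 13642 passed limma's test of the difference, against 258 at an unadjusted p under 0.05. These 258 are 1.89% of the genes, fewer than chance alone gives at that threshold, so they are no sign of a difference. Why this test gave so few was not tested. The smallest p were those of Rgs1, whose effect was larger at E16.5 by 1.10 (SE 0.23), Bank1, a scaffold protein of B cells (0.73, SE 0.17), and Msr1, a scavenger receptor of macrophages (0.65, SE 0.14), each with an adjusted p of 1.00. By camera, 8 of the 23 lists differed between stages, among them macrophage genes (median difference 0.46, adjusted p = 1.83e-08; adjusted p = 0.137 with an estimated correlation) and steroidogenic genes (median −0.19, adjusted p = 3.35e-06; adjusted p = 0.137 with an estimated correlation). Without control E16.5 replicate 1 camera no longer placed the subcapsular and sex composition lists apart but did so for erythroid (adjusted p = 0.000542) and interferon genes (0.00174), with adjusted p of 0.178 and 0.218 with an estimated correlation. Without replicate 2 it no longer did for capsule, proliferation and sex composition genes. With an estimated correlation no list passed, except macrophage genes without control E16.5 replicate 1 (adjusted p = 0.0485), and 1 member of any of the 23 lists, in the macrophage list, passed adjusted over the list alone.

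Over the day from E15.5 to E16.5 in control glands 6 genes rose and 7 fell, among the latter 2 embryonic globin genes and 2 genes of sterol synthesis. Hbb-y, an embryonic globin, fell by 3.71 (SE 0.61, adjusted p = 0.0254, n = 4 per group) and Hbb-bh1 by 1.82 (adjusted p = 0.0344). Cyp2f2 rose by 1.77 (SE 0.28) and the lipid transporter Abca8a by 1.44 (SE 0.23), each with an adjusted p of 0.0254. Bcan (1.00), the mannosidase Man1a (0.82) and Npy2r (0.75) rose, and the progenitor transcription factor Sox2 (−0.93) and the sterol synthesis enzymes Lss (−0.87) and Tm7sf2 (−1.05) fell. Each of these 10 genes lost its call in 5 or 6 of the 8 fits that left out 1 array. Tm7sf2 lost it also in 11 of 15 other settings, among them quantile normalization, both centrings and either covariate, and the other 9 genes in 2 to 4. Control E16.5 replicate 1 held Hbb-y at 11.93 against 8.33 to 9.10 in the other 3, and without it Hbb-y fell by 4.54. The embryonic globin Hba-x differed by −2.43 (adjusted p = 0.106), and by −3.08 (adjusted p = 0.00318) without that array. The same array stood apart from the other 3 for Abca8a and replicate 2 for Sox2.

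Proliferation genes were lower at E16.5 in controls as a list: 0 of 25 passed in limma, but 23 fell when adjusted over the list alone, the same number as at an unadjusted p under 0.05, with a median of −0.42 (camera adjusted p = 5.53e-26; adjusted p = 0.00253 with an estimated correlation). Of the cholesterol genes 2 of 20, Lss and Tm7sf2, fell and 17 did adjusted over the list alone (median −0.58, camera adjusted p = 6.07e-24; adjusted p = 0.0207 with an estimated correlation). Of 9 erythroid genes 2 fell, 3 adjusted over the list alone (camera adjusted p = 4.11e-05; adjusted p = 0.227 with an estimated correlation). No macrophage or let-7 target gene passed in limma, against 6 higher, and 1 higher and 4 lower, at an unadjusted p under 0.05. Adjusted over the list alone 4 macrophage genes rose (camera adjusted p = 1.24e-07) and 4 let-7 targets fell (camera adjusted p = 0.00229), each with an adjusted p of 0.0851 with an estimated correlation. With 1 array left out these 2 counts were 1 to 7 and 1 to 3; both were 1 without control E16.5 replicate 1 or control E15.5 replicate 1 and 2 without control E16.5 replicate 2, and 7 macrophage genes rose without control E16.5 replicate 3. Capsule genes were lower by camera (adjusted p = 0.0218) and p53 targets (0.0385) and interferon genes (0.0185) higher, with adjusted p of 0.445, 0.275 and 0.445 with an estimated correlation. In these 3 lists 0 members passed in limma by either count, against 2, 6 and 3 at an unadjusted p under 0.05. Of the 23 lists, those of proliferation and cholesterol genes passed with an estimated correlation. Without control E16.5 replicates 1 and 2, 9 proliferation and 15 cholesterol genes fell adjusted over the list alone. In limma 4 cholesterol and 3 erythroid genes fell without control E16.5 replicate 1 alone, 0 and 0 without replicate 2 alone (16 and 3 at an unadjusted p under 0.05), and 0 (16 at an unadjusted p under 0.05) and 3 without both.

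Several list calls for the day in controls changed when 1 array was left out. Without control E16.5 replicate 1 the camera adjusted p was 0.0631 for capsule genes, 0.135 for p53 targets, 0.0581 for let-7 targets and 0.253 for interferon genes, while erythroid genes passed with an estimated correlation (adjusted p = 0.0432) and the macrophage gene Ptprc rose by 0.60 (adjusted p = 0.0343). Without replicate 2 it was 0.0560 for capsule genes, and chromaffin (adjusted p = 4.84e-05) and steroidogenic genes (0.0247) were higher and machinery genes (0.0386) lower, with adjusted p of 0.283, 0.442 and 0.308 with an estimated correlation. The let-7 target Hmga2 fell by 0.75 (adjusted p = 0.0449) without control E15.5 replicate 4. When adjusted over the list alone 14 to 22 proliferation genes fell, fewest without control E15.5 replicate 1. By that count 4 p53 targets rose and 1 fell without control E16.5 replicate 4, and 2 interferon genes rose without control E15.5 replicate 4 or control E16.5 replicate 3.

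In limma, 13 of 13642 genes changed over the day in controls, 6 higher and 7 lower. This count was 0 without control E15.5 replicate 1, 2 or 3 (902, 903 and 1056 at an unadjusted p under 0.05), 2 without control E16.5 replicate 2, 1 without replicate 3 and 5 without replicate 4. It was 0 in a fit to the 8 arrays alone (828 at an unadjusted p under 0.05), 8 with the stricter filter and 1102 with arrayWeights.

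In KO glands 6 of 15 macrophage genes rose over the day, and the embryonic globin genes Hbb-y and Hba-x fell. Cd163, a scavenger receptor of macrophages, rose by 1.76 (SE 0.21, adjusted p = 0.000735, n = 4 per group), Lgals3 by 1.79 (SE 0.22, adjusted p = 0.000737), Ccl6 by 1.44 (adjusted p = 0.00308), the ectonucleotidase Nt5e by 1.55 (adjusted p = 0.000735) and H2-Aa, a class II histocompatibility gene, by 2.06 (SE 0.44, adjusted p = 0.0347), with KO E15.5 replicate 3 at 4.52 and the other 3 at 6.47 to 6.74. Hbb-y fell by 2.80 (adjusted p = 0.0380) and the embryonic globin Hba-x by 2.58 (adjusted p = 0.0226). The protease Prss35 fell by 0.77 (adjusted p = 0.0169; KO E15.5 replicate 3 stood at 10.72 and the other 3 at 10.03 to 10.05) and the pyrophosphatase Ppa1 by 0.42 (adjusted p = 0.0498). The calls of H2-Aa, Hbb-y, Hba-x, Prss35 and Ppa1 were lost in 2 to 8 of the 8 fits that left out 1 array.

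The 6 macrophage genes, 13 adjusted over the list alone, included C1qb (1.14) and Tyrobp (1.03), and the list's median was 0.77 (camera adjusted p = 1.79e-19; adjusted p = 0.0115 with an estimated correlation). They numbered 3 without KO E16.5 replicate 3, and the call of Tyrobp was lost in 4 of the 8 fits that left out 1 array. The Schwann list had 0 of 6 passing in limma, against 3 at an unadjusted p under 0.05 and 3 higher adjusted over the list alone (camera adjusted p = 0.00100; adjusted p = 0.0297 with an estimated correlation). For proliferation genes 0 of 25 passed by either count, against 5 lower at an unadjusted p under 0.05 (median −0.26, camera adjusted p = 4.44e-09; adjusted p = 0.0533 with an estimated correlation). For cholesterol genes 0 of 20 passed and 2 fell adjusted over the list alone, against 9 at an unadjusted p under 0.05 (camera adjusted p = 9.00e-09; adjusted p = 0.170 with an estimated correlation). Of 9 erythroid genes 2 fell, 3 adjusted over the list alone (camera adjusted p = 0.00904; adjusted p = 0.344 with an estimated correlation).

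Camera also placed interferon (adjusted p = 1.20e-05), chromaffin (0.0124), subcapsular (0.0143) and p53 target (0.0346) genes higher and steroidogenic genes (0.00915) lower at E16.5 in KO, with adjusted p of 0.147, 0.561, 0.260, 0.244 and 0.344 with an estimated correlation. In limma 0 members of these 5 lists passed, against 6, 5, 2, 4 and 3 at an unadjusted p under 0.05, and adjusted over the list alone 1, 1, 0, 0 and 1 did. Leaving out an array moved several counts adjusted over the list alone. The Schwann count was 1 without KO E15.5 replicate 2, 3 or 4 or KO E16.5 replicate 3 or 4, both cholesterol calls were lost in 6 of 8 such fits, and without KO E15.5 replicate 4 the falls numbered 5 in the cholesterol and 3 in the steroidogenesis list and 3 interferon genes rose, as they did without KO E16.5 replicate 3. In limma such fits added Aif1, Cd44 and Ifit3 (without KO E15.5 replicate 4) and Cdh19 (without KO E16.5 replicate 1), all higher at E16.5.

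In limma, 123 genes changed over the day in KO glands, 119 higher and 4 lower. The count was 68 without KO E15.5 replicate 1, 56 without replicate 2, 78, 53 and 72 without KO E16.5 replicate 2, 3 and 4, 73 in a fit to the 8 arrays alone and 435 with arrayWeights. Whether the day's change differed between genotypes is the same test as the difference of the KO effects, in which 0 genes passed.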

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

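The tests of young embryos in a pool, and of macrophage genes against the genes of other cell types and against erythroid genes, and the admixture share with 3 controls as reference, were chosen only after the result was seen; the admixture test with 2 controls and the offset test were set down earlier.

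Of 200 groups of 4 arrays examined for array-wide values and named genes, 12 held an array far from the other 3; chance gives about 1 in 20, here 10. Control E16.5 replicate 1 stood apart for Nr6a1 (7.75, the other 3 from 5.71 to 5.87), Hba-x (8.22, others 5.57 to 5.67) and Abca8a (8.55, the nearest other 8.96). Control E16.5 replicate 2 stood apart for Pcna (11.05, others 12.61 to 12.72), Sox2 (6.13, others 6.54 to 6.57) and the mean over all probe sets (6.32 against 6.31 in the other 3). Control E16.5 replicate 4 stood apart for Aard (7.18, others 7.89 to 8.02) and Trim6 (5.59, others 4.83 to 4.85). Among KO arrays, E15.5 replicate 3 stood apart for H2-Aa (4.52, others 6.47 to 6.74) and Prss35 (10.72, others 10.03 to 10.05). KO E16.5 replicate 2 did so for Ppp1r36 (6.53, others 6.20 to 6.24) and replicate 4 for Man1a (8.39, others 8.58 to 8.62).

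Nr6a1 in control E16.5 replicate 1 lay 0.319 of the way from control replicates 3 and 4 to the KO mean on the linear scale, with replicate 2 left out of the reference, where KO tissue or RNA in that pool could have put it. Such an admixture would move all KO-dependent transcripts by a like share. It was measured over 115 other genes that passed at E15.5, changed at least 2-fold and did not overlap between genotypes. Their median share was 0.0497 (95% interval 0.0214 to 0.105), and 0.0369 (−0.0179 to 0.102) with replicate 2 in the reference, which argues against a share as large as that of Nr6a1. The intervals come from resampling genes, which are not independent, within this array, so they leave out variation between pools. Single genes lay on either side, with Frzb at 0.261, Akr1d1 at 0.105, Igdcc3 at 0.0236, Acvr1c at −0.0876 and Trim6 at −0.0901. Embryos as young as E15.5 are argued against for Nr6a1, since the highest of the 4 control E15.5 arrays stood at 5.79 (SD 0.0976), although Hba-x at 8.22 in this array lay towards the control E15.5 mean of 8.71. Apart from the stage of the embryos no biological explanation was tested, and the value stays unexplained.

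By camera, 8 lists had a KO effect that differed between stages, and none of the 8 passed with an estimated correlation on all arrays (macrophage genes did without control E16.5 replicate 1, adjusted p = 0.0485). The effect was larger at E16.5 for macrophage genes (adjusted p = 1.83e-08, median difference 0.46; adjusted p = 0.137 with an estimated correlation). Steroidogenic genes had a lower effect at E16.5 (adjusted p = 3.35e-06, median −0.19; adjusted p = 0.137 with an estimated correlation). Cholesterol genes had a higher effect (adjusted p = 3.35e-06, median 0.28; adjusted p = 0.221 with an estimated correlation), as did proliferation genes (adjusted p = 3.68e-06, median 0.21; adjusted p = 0.137 with an estimated correlation). The effect was also higher at E16.5 for subcapsular (adjusted p = 0.00636, median 0.17), Schwann (adjusted p = 0.0199, median 0.16) and capsule genes (adjusted p = 0.0307, median 0.10), with adjusted p of 0.221, 0.137 and 0.441 with an estimated correlation. The sex composition list differed with an adjusted p of 0.0472 (median −2.08; adjusted p = 0.221 with an estimated correlation).

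Macrophage genes were higher in KO glands at E16.5 (adjusted p = 0.0237 with an estimated correlation, 0.0569 without control E16.5 replicate 2; at E15.5 it was 0.0971, and 1 member passed with the offset allowed for), and a smaller share of cortex cells, more residual blood or the offset between genotypes could account for this. A smaller cortex would raise the markers of all other cell types alike, yet at E16.5 the macrophage mean minus that of chromaffin, endothelial and capsule genes was higher in KO by 0.867, with all 4 KO arrays (lowest −1.10) above all 4 controls (highest −1.51), which argues against it as the whole cause. An offset of the size seen in dim probe sets is argued against. The list's median of 1.32 lay above all of 10000 medians of random sets of such probe sets, of which the highest was 0.294. The macrophage genes passed the filter on dim probe sets, however, and changes near the floor are understated. The random sets were also not chosen to vary together as members of a list may. The size of an offset among brighter genes was therefore not measured. Blood cannot be told apart, because the macrophage mean minus the erythroid mean was higher in KO by 0.589 but the lowest KO array (1.59) lay below the highest control (1.67), and without control E16.5 replicate 1 erythroid genes were higher in KO as well (2 of 9 passed; camera adjusted p = 0.00584, and 0.292 with an estimated correlation). The fit without that control array kept KO E16.5 replicate 1, whose Hbb-y was also high (11.91). A rise of macrophages with the loss of Dicer in the gland stays open as a hypothesis, found and examined on the same arrays.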

How the results depend on the processing

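The allowance for the genotype offset, the fits without control E16.5 replicates 1 and 2 and the fits without X and Y genes were chosen only after the result was seen; the other alternatives were planned. Of 131 counts recomputed under an alternative, 98 stayed within 1.5 times. These include counts of the difference between stages that stayed at 0, such as all those with 1 array left out. Of 12642 values of single genes 12106 kept their side of the threshold, 341 lost and 195 gained a call. Of 1063 values of gene lists 895 kept it, 140 lost and 28 gained a call. None that passed in either fit changed direction. Changes of direction among values that passed in neither fit were not counted. The 20 genes named at each stage for KO against control by size of change kept their call under all settings in which they were tested, the offset included. Besides the fits without 1 array, Cited1, Ppp1r36, Slc7a11 and Ibsp were tested in 15 settings at E15.5, and the others in 16. At E16.5 Anxa13, Rgs1 and Ppp1r36 were tested in 16 such settings, and the others in 17.

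At E15.5 the 800 genes became 1688 without the filter and 414 with the stricter filter, 1350 with arrayWeights, 118 with the offset allowed for and 117 at a change of at least 2-fold. At E16.5 the 1439 became 2355, 899, 4938, 251 and 208 in the same order, 926 with the sex score as a covariate and 817 in the fit to 8 arrays. The difference between stages gave 6 genes with arrayWeights against 0 (258 at an unadjusted p under 0.05 in limma, fewer than chance gives). For the day in controls, the 13 genes became 8 with the stricter filter, 1102 with arrayWeights, 4 without control E16.5 replicates 1 and 2, 0 in the fit to 8 arrays (828 at an unadjusted p under 0.05) and 6 at 2-fold. For the day in KO the 123 became 435 with arrayWeights, 73 in the fit to 8 arrays and 29 at 2-fold. The genes that the stricter filter removed had an unadjusted p under 0.05 more often than those it kept, 29.3% against 16.3% at E15.5 and 31.5% against 22.1% at E16.5, while for the day the shares were 7.73% against 7.88% in controls and 9.91% against 9.40% in KO. With the offset allowed for, the shares were 12.4% against 5.31% at E15.5 and 14.3% against 7.37% at E16.5. The allowance thus left a higher share among the dimmer genes, and the cause was not tested. The 2-fold threshold admits fewer genes, the 8-array fits have fewer arrays, and the offset widens each SE. The arrayWeights fit gave control E16.5 replicate 3 a weight of 10.4 and replicate 2 0.193. For arrayWeights, the sex score and control E16.5 replicates 1 and 2 the cause was not tested.

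Leaving out 1 array at a time gave 588 to 666 genes at E15.5, lowest without control replicate 2, and 935 (without KO replicate 3) to 1705 (without control replicate 2) at E16.5. The difference between stages stayed at 0 (198 to 601 at an unadjusted p under 0.05 in limma, fewer than chance gives). The day in controls ranged from 0 to 19: 0 without control E15.5 replicate 1, 2 or 3 (902, 903 and 1056 at an unadjusted p under 0.05), 2, 1 and 5 without control E16.5 replicate 2, 3 and 4, and 19 without control E15.5 replicate 4. The day in KO ranged from 53 (without KO E16.5 replicate 3) to 146 (without KO E15.5 replicate 4), with 68 and 56 without KO E15.5 replicate 1 and 2 and 78 and 72 without KO E16.5 replicate 2 and 4. Each such fit had fewer arrays; which property of an array moved the count was not tested.

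With the replicate number within a stage as a block, the counts were 710, 1263 and 0 (333 at an unadjusted p under 0.05 in limma) for the KO effects and their difference. Same-numbered pools deviated together with r over 0.1 in 5 of 8 pairs (−0.39 to 0.45), and 3 of 8 controls correlated best with the KO pool of their own number, so the numbers were not taken to pair the pools. Pools of both genotypes came from the same litters, but which number is which litter is not given in the sources used here, and replicate 1 of both genotypes held the highest Hbb-y at E16.5 (11.93 and 11.91, others 8.33 to 10.16). Signal over background limits what can be seen of dim transcripts: 4551 of 18193 genes lay below the filter.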

Other observations

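The quantile test of a rise of most transcripts and the test on bacterial probe sets were chosen only after the result was seen, as was the list of muscle genes; the other tests of this part were planned.

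Liver transcripts varied between pools of the same group. Alb, the serum albumin gene of liver, ranged from 7.14 in KO E16.5 replicate 3 to 12.41 in KO E16.5 replicate 2, and Ttr, a liver-derived carrier of thyroid hormone, from 5.84 to 12.02 in the same 2 arrays. The pools also differed in sex: Eif2s3y, which lies on the Y chromosome, stood at 3.44 in control E15.5 replicate 4 and 3.22 in KO E16.5 replicate 1, against 8.41 to 9.64 in the other 14 arrays. Xist stood at 5.17, 4.96 and 4.85 in control E15.5 replicates 1, 2 and 3. It stood at 4.82 and 4.62 in control E16.5 replicates 3 and 4, and at 5.02 in KO E15.5 replicate 2. In all other arrays it lay between 10.37 and 12.76. At each stage low Xist was thus seen in more control than KO pools. In control E16.5 replicate 2 all 12 genes of a list of skeletal and cardiac muscle transcripts stood above their highest value in the other 15 arrays, with a mean of 11.74 against 5.41 to 8.91. Examples were Tnnc2 (12.87 against at most 9.59), Mylpf (12.76 against 9.87), Actc1 (12.96 against 10.75) and Acta1 (12.33 against 10.53). The list was chosen after these values were seen, and no explanation was tested.

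Among the 9008 dimmest probe sets, 31.7% at E15.5 and 28.3% at E16.5 had an unadjusted p under 0.05 for KO against control, against 2.13% for the difference between stages. With the offset allowed for, 118 and 251 genes passed, and 5.06% and 5.16% of these probe sets had such a p. Those shares do not check the allowance, since it was estimated from the same probe sets. An even shift of whole arrays does not account for this excess. After quantile normalization 26.0% of the dimmest probe sets still had an unadjusted p under 0.05, a mean of the 2 stages. A rise of most transcripts in the knockout by unequal amounts could leave such a share too, so this test cannot decide on it. Expression differences of the genes behind these probe sets cannot be told apart by counts among 27 bacterial probe sets at background, which no mouse gene feeds. Of these, 5 had an unadjusted p under 0.05 for the mean KO effect over the 2 stages (18.5%, exact 95% interval 6.30 to 38.1, against 43.8% of the dim probe sets). At each stage 3 did (11.1%, 2.35 to 29.2), which chance could give. Their KO effects at the 2 stages correlated with r = 0.672, however, and 0 had an unadjusted p under 0.05 for the mean day effect. Whether mouse transcripts could move these probe sets indirectly was not tested, and r was not tested against chance. The bacterial probe sets are few, and several stand for the same transcript. Neither r nor the exact intervals therefore rest on independent values. Normalization of control and KO arrays in separate runs cannot be told apart either. Across the 9008 dimmest probe sets the KO effects at the 2 stages, which share no array, correlated with r = 0.767, which separate runs could give. The day effects correlated with r = 0.101, however, where under 0.1 had been set for separate runs. A hybridization batch that follows genotype would leave the same trace, and no batch is given in the sources used here.

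In the fit to all 16 arrays, other splits of the 8 arrays compared into 4 and 4 did not reach the real counts. For KO against control at E15.5 1 of 35 splits, the real one, gave 800 genes and the highest other gave 0. At E16.5 1 of 35 gave 1439 and the highest other gave 9, and for the day in KO 1 of 35 gave 123 genes and the highest other 0. A share of 1 in 35 is the smallest that these splits allow. The other splits also leave the real difference in their residual spread, which lowers their counts. The splits alone therefore do not exclude chance in any of these comparisons. For the day in controls 1 of 35 splits gave the 13 genes and the highest other gave 1, but the count was 0 in a fit to those 8 arrays alone and without control E15.5 replicate 1, 2 or 3 (828, 902, 903 and 1056 at an unadjusted p under 0.05 in limma), so these 13 calls are weakly supported. For the difference between stages 100 of 100 drawn splits gave as many as the real 0 genes (258 at an unadjusted p under 0.05 in limma, fewer than chance gives), with at most 3 in another split. This decides nothing, since any split reaches a count of 0.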
